A study of Sus scrofa with 21 samples.

How the data were processed

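The samples were distal small intestine of 21 piglets (Sus scrofa, Danish Landrace/Yorkshire), taken at euthanasia at 24 to 25 days of age. The sample titles name 10 control and 11 treatment piglets, and the design text gives 10 piglets on normal milk replacer and 11 on replacer with starch, which the growth protocol describes as added wheat. The treatment piglets are called starch 1 to 11 here. The labels give no sex, litter, batch or sequencing date. Per the labels' protocols, total RNA was extracted with miRNAeasy kits and sequenced by the provider's standard protocol. No further library detail, strand setting or read length is given in the sources used here.

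The authors deposited 1 file per piglet with a row per transcript. Per the file headers each row holds a transcript and gene identifier of the Ensembl pig annotation, a length, an expected count (an estimated count that need not be whole) and an FPKM value (fragments per kilobase of transcript, scaled to depth). The deposited expected counts were not normalised, and the deposited FPKM values had been scaled by the authors for length and depth. Per the submitters' processing notes HISAT and DESeq2 were used, without a version or a role, and the genome build and the counting program are not given in the sources used here. Transcripts with no expected count were not listed for a piglet and were taken as 0. Nearly all transcript lengths were multiples of 3 (99.96 to 99.97% per file), so the lengths are coding lengths without untranslated regions. Reads shared by near-identical genes were divided by the authors' estimate, and 27 tested genes had counts identical to those of another gene, so such copies are uncertain.

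Expected counts were summed over the transcripts of each gene and rounded to whole numbers. The files held 39105 transcripts of 18661 genes, of which 14276 (76.5%) matched a symbol in the table of pig gene names. No reference genome was used, and no coordinates are reported. Per-piglet totals of 6719264 to 8610458 expected counts set the counting error, which is small beside the spread between piglets for abundant genes and larger for genes near the filter.

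The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) on the diet groups and diet as the only term, over all 21 piglets. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are log2, starch minus control, with standard errors and 95% confidence intervals from the same fit. CPM values are given as mean ± SD over piglets. The gene lists, 42 in all, covered nutrient digestion, immunity, cell types of the gut wall and sample handling. Those with at least 5 tested members (40) were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. Red blood cell markers (4 tested members, mean log2 fold change 0.13) were too few for the test, and genes of pancreas and stomach had 0 members past the filter. Camera with an estimated correlation and fry were run beside it. A list score per piglet is the mean over members of log2 CPM (prior count 2) centred over the 21 piglets. Principal components were computed from log2 CPM of the 500 most variable tested genes, and mean scores, depth and composition were compared between the diets by two-sided permutation tests with 100000 resamples.

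The named genes follow a rule fixed before the data were examined. It takes 7 genes of sugar digestion and uptake (SI, MGAM, LCT, TREH, SLC5A1, SLC2A2 and SLC2A5), then 12 genes per direction by fold change among those past the threshold, filled up by smallest p where fewer passed, and up to 4 members with the smallest p of each list described. Genes named for the components and for single piglets were chosen after their values were seen. Some genes are not reported here.

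The alternatives fixed in advance were upper-quartile and RLE scaling, DESeq2 1.42.0, voom with sample quality weights, limma on log2(FPKM + 0.5), log2(FPKM + 0.1) and log2(FPKM + 1) for genes with FPKM of at least 1 in 10 piglets, no filter, a filter at a mean of 1 CPM, transcripts in place of gene sums, the replicate number as a block, surrogate variables (sva 3.50.0), the smooth muscle and B-cell scores as covariates, components from all tested genes, and leaving out each piglet in turn. Others were added after seeing the data. These left out the 3 piglets that stood apart on component 1 (also with an estimated correlation), used Y-linked expression as a covariate, used robust dispersions, left out mitochondrial genes before scaling, and refitted the samples of the block without it. The tests were first checked on counts simulated from the real means and library sizes with known changes. With no change simulated, the edgeR test called 0 genes and gave an unadjusted p below 0.05 for 4.8% of genes. Figures were drawn with matplotlib.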

Results

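RNA sequencing was performed on distal small intestine of 21 Danish Landrace/Yorkshire piglets at 24 to 25 days of age. The control group (n = 10) had been fed a milk replacer, and the starch group (n = 11) the same product with wheat added as a source of starch. The files listed between 15702 and 16335 genes per piglet, and the total expected count per piglet lay between 6719264 and 8610458, with 7549038 ± 535974 in the control group (SD, n = 10) and 7960469 ± 483641 in the starch group (SD, n = 11; two-sided permutation test, p = 0.0828). After the filter on low counts 13127 genes were tested. Log2 CPM of all tested genes correlated between any pair of piglets with r between 0.739 and 0.973, across genes, which are not independent replicates. The median r was 0.929 for piglets of the same diet and 0.933 for piglets of different diets.

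The design compared the diets to ask how added starch alters gene expression in the gut of milk-fed piglets. The genes closest to that question, those for the enzymes and carriers that handle dietary sugars, did not differ between the diets by more than the spread between piglets. MGAM, which encodes maltase-glucoamylase, the brush-border enzyme that releases glucose from starch fragments, read 105 ± 98.6 CPM in control (SD, n = 10) and 231 ± 222 CPM in starch piglets (SD, n = 11). The log2 fold change, given throughout as starch minus control, was 1.14 (SE 0.64, 95% confidence interval -0.19 to 2.47, unadjusted p = 0.0898, adjusted p = 0.9998 in the edgeR quasi-likelihood test). SI, encoding sucrase-isomaltase, read 703 ± 551 CPM in control and 910 ± 608 CPM in starch piglets, a log2 fold change of 0.37 (95% interval -0.95 to 1.70). The glucose carriers SLC5A1 of the brush border and SLC2A2 of the basolateral membrane had log2 fold changes of 0.26 (95% interval -0.78 to 1.30) and 0.42 (-0.76 to 1.59), and the fructose carrier SLC2A5 one of -0.14 (-0.82 to 0.54). All 5 genes spanned a wide range between piglets of one diet. MGAM, for example, ran from 5.56 CPM in starch 3 to 820 CPM in starch 7, and without starch 7 its log2 fold change was 0.71. Without starch 7 the value of SI was 0.17, that of SLC5A1 0.03, that of SLC2A2 0.29 and that of SLC2A5 -0.29, and over all alternatives they ran from 0.17 to 0.80, from 0.03 to 0.61, from 0.25 to 0.91 and from -0.38 to 0.06. The lowest value of SLC2A2, 0.25, was that without starch 5. Trehalase, TREH, had at most 31 counts in any piglet and was not tested, and lactase, LCT, was not analysed here. Over the 15 tested genes of the list for carbohydrate digestion and sugar transport, 9 were higher and 6 lower on starch, with a mean log2 fold change of 0.10 (camera with the preset correlation, adjusted p = 0.33; adjusted p = 0.915 with an estimated correlation). With the preset correlation the list passed in 4 of 33 alternatives, without control 2 (mean 0.23, adjusted p = 0.0114), without control 6 (0.18, adjusted p = 0.0392), without starch 3 (0.18, adjusted p = 0.00554) and with the smooth muscle score as a covariate (0.31, adjusted p = 0.0477).

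**Figure D1:**
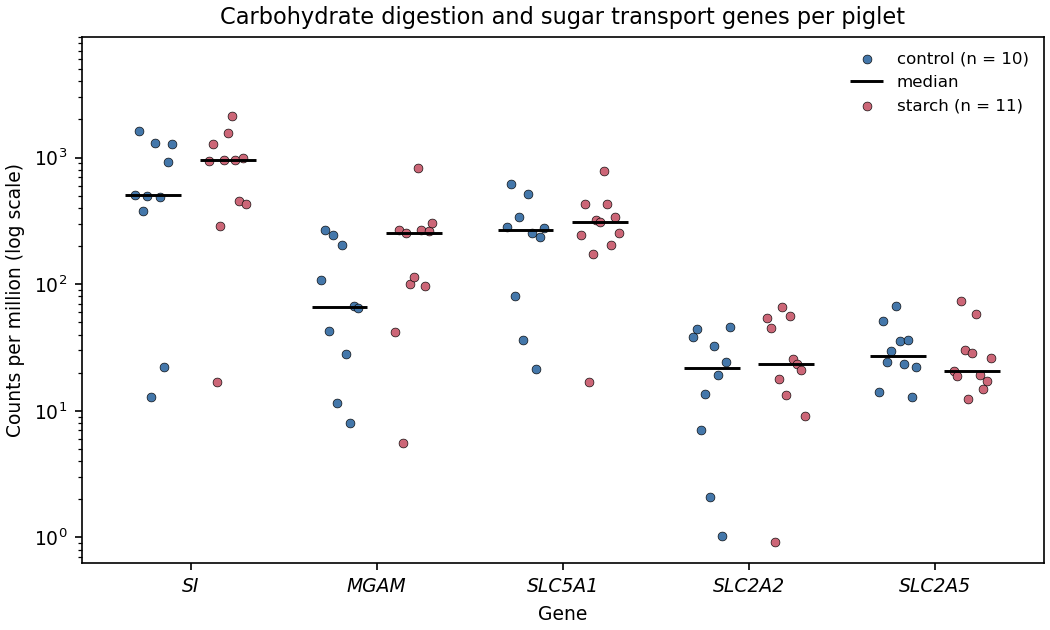
CPM on a log axis for the sucrase-isomaltase, maltase-glucoamylase and sugar carrier genes in each piglet, with control piglets (n = 10) on the left and starch piglets (n = 11) on the right of each gene and the median of each group as a bar. The groups overlap at every gene, and starch 3 is the lowest starch piglet at SI, MGAM, SLC5A1 and SLC2A2.

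Across the transcriptome, 0 of 13127 genes differed between the diets at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and the smallest adjusted p was 0.9998. At an unadjusted p of 0.05 there were 174 genes, 1.33% of those tested, where the nominal rate would give 656. Of these 174 genes, 53 were higher and 121 lower on starch. In random splits of the piglets into groups of 10 and 11, a comparison chosen later, the count ran from 65 to 4610. Of 100 splits, the real one included, 91 gave 174 or more. DESeq2, run on 18630 genes without the filter, also called 0 genes. It gave 293 (1.57%) at an unadjusted p of 0.05 and a smallest adjusted p of 0.211. On the 13127 filtered genes voom called 0, with 268 (2.04%). In counts simulated from the means, dispersions and depths of these libraries, with genes varying independently, the edgeR test recovered 14.9% of genes changed 1.5-fold. It recovered 71.6% of those changed 2-fold and 100% of those changed 4-fold. Most changes of 1.5-fold in single genes were thus not detectable here. With no change simulated, 4.8% of genes had an unadjusted p below 0.05, against 1.33% in the real fit. The simulated shares therefore need not hold for the real libraries. There the edgeR test gave MGAM (log2 fold change 1.14) and AFF2 (2.03) an adjusted p of 0.9998. The common biological coefficient of variation was 40.3%. Leaving out control 5, control 8 and starch 3, the libraries that stood apart on component 1, also gave 0 genes, with 382 at an unadjusted p of 0.05.

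The genes with the smallest unadjusted p in each direction are given as values, since none passed the threshold. Lowest among them was that of IGSF9, a cell adhesion molecule of the immunoglobulin superfamily, at 12.9 ± 5.91 CPM in control and 6.25 ± 1.60 CPM in starch piglets (log2 fold change -1.04, SE 0.23, unadjusted p = 0.000139). CHST9, a sulfotransferase acting on N-acetylgalactosamine residues, had a log2 fold change of -0.94 at 2.72 ± 0.91 against 1.41 ± 0.48 CPM, and CNTNAP4 and SLC12A8 had values of -1.13 and -1.03 at means below 3 CPM in both groups. More abundant genes on this side were AAK1, an endocytic kinase (-0.60, 45.2 ± 15.7 against 29.7 ± 7.38 CPM), FAF2 (-0.40, 42.0 ± 10.6 against 31.8 ± 5.21 CPM) and FERMT1, the epithelial kindlin (-0.67, 57.6 ± 34.4 against 36.2 ± 9.53 CPM). The rest were LUZP2 (-0.79), LZTS1 (-0.56), PRDM6 (-0.66), PUSL1 (-0.69) and MOXD1 (-0.54). On the other side, CRYZL1 had the smallest p (log2 fold change 0.34, 10.5 ± 2.14 against 13.3 ± 1.46 CPM, unadjusted p = 0.00905). RRM2B, a subunit of the p53-inducible ribonucleotide reductase, had a log2 fold change of 1.33 with 1.79 ± 1.10 against 4.52 ± 4.70 CPM. Of the others, NUGGC (1.81), AFF2 (2.03) and FCRL1 (1.66) had SDs above their means on starch, and PLCG2, a phospholipase of B-cell receptor signalling, had 0.49 at 68.6 ± 17.2 against 96.2 ± 39.8 CPM. RRM2B, NUGGC, AFF2, FCRL1, PLCG2, BICDL1 and MED24 were highest in starch 9 and starch 10. AFF2 read 31.8 and 55.5 CPM in them and at most 2.60 CPM in any other starch piglet, and FCRL1 read 16.7 and 30.6 CPM against at most 2.59 CPM. The values were 88.0 and 95.5 CPM for NUGGC (next starch piglet 37.7), 10.7 and 16.2 CPM for RRM2B (next 4.92) and 155 and 185 CPM for PLCG2 (next 109). They were closer for BICDL1, at 4.14 and 5.36 CPM (next 3.63), and for MED24, at 56.1 and 50.0 CPM (next 49.8). ATP8, encoded by the mitochondrial genome, had 0.48, and ASB6 (0.27), BICDL1 (0.70), POLR3K (0.35), MRPL49 (0.39) and MED24 (0.19) completed the group.

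Sets of genes were tested as lists fixed in advance. Of 40 lists with at least 5 tested members, 6 passed at an adjusted p of 0.05 in camera with the preset correlation of 0.01. Those of mitochondrially encoded transcripts, cholesterol biosynthesis, B cells and germinal centres, antigen presentation and the cell cycle were higher on starch, and that of goblet cells and mucus was lower. With a correlation estimated from the data 0 lists passed, the smallest adjusted p being 0.693. Fry, which asks whether a list's genes move on balance one way, also passed 0 lists (adjusted p = 0.943 for each of the 6). Among the members of all lists, 0 genes passed over all genes tested and 0 when adjusted over the list alone.

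The goblet cell list had 12 of its 13 tested members lower on starch and a mean log2 fold change of -0.41 (adjusted p = 2.36e-06 with the preset correlation; adjusted p = 0.693 with an estimated correlation). MUC2, the secreted mucin that forms the intestinal mucus gel, read 425 ± 312 CPM in control and 253 ± 127 CPM in starch piglets (log2 fold change -0.75, 95% interval -1.43 to -0.06), and CLCA1, a mucus-processing protease, 491 ± 250 and 330 ± 152 CPM (-0.57). BCAS1 and the goblet cell transcription factor SPDEF had values of -0.53 and -0.56. Control 5 and control 8 held the highest scores of the list, 0.71 and 1.34, on the scale of mean centred log2 CPM. With no filter on low counts, where up to 14 members could enter in place of 13, the mean was -0.12. That value also rests on genes of very low count, and the list still passed there with the preset correlation. Without control 8 the mean log2 fold change was -0.19 (adjusted p = 0.00847). Without control 5, control 8 and starch 3 it was -0.11 and the list no longer passed (adjusted p = 0.0653).

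All 13 mitochondrially encoded messages were higher on starch, with a mean log2 fold change of 0.30 (adjusted p = 2.96e-09 with the preset correlation; adjusted p = 0.712 with an estimated correlation). ATP8 (0.48), ATP6 (0.41), ND3 (0.44) and ND6 (0.45), components of ATP synthase and of complex I, had the smallest p among them. They made up 16.4 ± 1.77% of counts in control (SD, n = 10) and 19.0 ± 3.81% in starch piglets (SD, n = 11; permutation test, p = 0.0643), with the highest share, 26.4%, in starch 6. The 20 most abundant genes of each library took 22.9 ± 1.75% and 25.7 ± 3.72% of counts (permutation test, p = 0.0448). Mitochondrial messages such as ATP6, at means of 18370 CPM in control and 24400 CPM in starch piglets, count towards both shares. The shares are therefore not separate results, and neither p was adjusted for the number of quantities compared. The mitochondrial list was written as one of sample handling. The list of nuclear genes of oxidative phosphorylation had a mean log2 fold change of 0.05 and did not pass (adjusted p = 0.33; adjusted p = 0.915 with an estimated correlation). It passed without control 6 (0.09), control 8 (0.11), starch 5 (0.11) or starch 10 (0.09), with voom (0.08) and with surrogate variables (0.09), at adjusted p from 0.00162 to 0.0486.

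The cholesterol biosynthesis list had 16 of 20 members higher and a mean log2 fold change of 0.17 (adjusted p = 0.000715 with the preset correlation; adjusted p = 0.915 with an estimated correlation). Among its members, MSMO1, a sterol oxidase, had a log2 fold change of 0.36 (95% interval -0.14 to 0.86). LSS, encoding lanosterol synthase, read 57.0 ± 15.3 CPM in control and 65.5 ± 15.3 CPM in starch piglets (0.20), and SC5D had a value of 0.26. The call was lost without control 1 (mean 0.11, adjusted p = 0.0826) and without starch 4 (mean 0.07, adjusted p = 0.149).

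Of the B-cell list all 16 members were higher on starch, with a mean log2 fold change of 0.90 (adjusted p = 0.000715 with the preset correlation; adjusted p = 0.915 with an estimated correlation). CD79A and CD79B, the signalling chains of the B-cell receptor, had values of 1.80 and 1.93, CD22 one of 1.36 and the B-cell coactivator POU2AF1 one of 1.60. Levels differed widely between piglets. The score of the list was 2.74 in starch 10, 2.43 in starch 9 and 1.09 in control 1, while 7 of 11 starch piglets and 7 of 10 control piglets lay below 0, and the median score was -0.26 on starch and -0.28 in control. CD79A read 73.7 CPM in starch 10 and 57.8 CPM in starch 9, against a median of 2.41 CPM over the 21 piglets. Without starch 9 the mean log2 fold change was 0.58 (adjusted p = 0.249), and without starch 10 it was 0.42 (adjusted p = 0.453). It was 0.14 with voom (adjusted p = 0.248) and -0.14 with surrogate variables in the model (adjusted p = 0.847), and 0.43 with Y-linked expression as a covariate (adjusted p = 0.0092). With the replicate number as a block the list did not pass, though it passed for the same piglets without the block.

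The antigen presentation list had all 16 tested members higher, with a mean log2 fold change of 0.27 (adjusted p = 0.00694 with the preset correlation; adjusted p = 0.915 with an estimated correlation). Its smallest p values belonged to PSMB8 and PSMB9 of the immunoproteasome (0.43 and 0.34), the peptide transporter gene TAP1 (0.39) and the class II gene SLA-DQB1 (0.36). The median score per piglet went the other way, at -0.10 on starch and 0.08 in control. The cell cycle list had 19 of 21 members higher and a mean of 0.17 (adjusted p = 0.00929 with the preset correlation; adjusted p = 0.915 with an estimated correlation), with TYMS at 0.41, BUB1B at 0.34, PLK1 at 0.36 and AURKB at 0.34. Both calls were lost without control 1, control 7, starch 3, starch 4 or starch 11, the antigen presentation call also without control 10, and the cell cycle call also without control 6, starch 9 or starch 10. In these leave-one-out fits the antigen presentation mean was 0.15 to 0.23 (adjusted p from 0.0622 to 0.348) and the cell cycle mean 0.08 to 0.13 (adjusted p from 0.0799 to 0.35). With the smooth muscle score as a covariate the antigen presentation call was lost too (mean 0.24, adjusted p = 0.0518), and it was also lost with voom. Both calls were lost with surrogate variables and with the B-cell score as a covariate. They were lost with the replicate number as a block too, but that fit leaves out starch 11, without which both were lost already. The cell cycle mean was larger without control 8 (0.34), without starch 5 (0.27) and without control 5, control 8 and starch 3 (0.40).

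**Figure D2:**
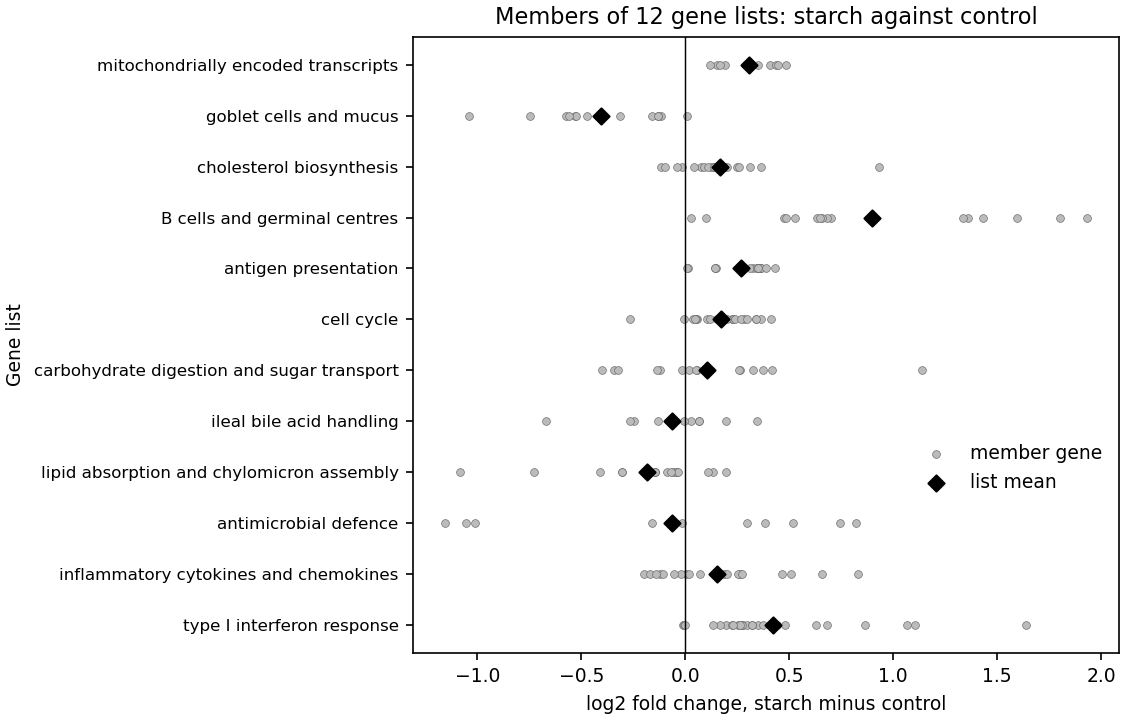
Log2 fold change, starch minus control, of each tested member (grey) and the mean (black) for the 6 lists that passed in camera with the preset correlation (upper rows) and for 6 of the lists that did not (lower rows). All 13 mitochondrially encoded messages and all 16 members of the B-cell list lie above 0, and 12 of 13 goblet cell genes lie below it.

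The other 34 lists did not pass, but 21 of them passed with the preset correlation in at least 1 of 33 alternatives. With an estimated correlation the adjusted p of these 21 was 0.915 to 0.95. That of ileal bile acid handling had 5 members higher and 5 lower, with FABP6, the ileal bile acid binding protein, at 0.34 and FGF19, the bile acid induced hormone, at -0.67 (95% interval -2.17 to 0.83). Lipid absorption and chylomicron assembly had 14 of 17 members lower (mean -0.19, adjusted p = 0.565), led in size by FABP2 (-1.09, 95% interval -2.63 to 0.46). It passed without control 5 (-0.29, adjusted p = 0.00688), without control 8 (-0.27, adjusted p = 0.00854) and without control 5, control 8 and starch 3 (-0.29, adjusted p = 2.04e-05), against an adjusted p = 0.915 with an estimated correlation. The mean score of this list per piglet went the other way, at 0.04 ± 1.38 on starch and -0.04 ± 1.72 in control (SD). The median score did not, at 0.38 on starch and 0.65 in control. Antimicrobial defence had 5 higher and 5 lower, with DUOX2 at -1.16 and the nitric oxide synthase NOS2 at 0.75 (adjusted p = 0.918). DUOX2 read 112 CPM in control 5 and 68.5 CPM in control 8, against a median of 7.17 CPM over the 21 piglets. Its highest starch value was 27.3 CPM, in starch 4. Inflammatory cytokines and chemokines had 12 of 19 members higher (adjusted p = 0.662). The type I interferon list had 24 of 27 members higher and a mean of 0.42 (adjusted p = 0.0662), with OASL at 1.64, MX2 at 1.07 and RSAD2 at 1.11. OASL read 215.7 CPM in starch 9 and 146.6 CPM in starch 7, against a median of 2.90 CPM over the 21 piglets. RSAD2 read 292.5 and 146.9 CPM in them (median 8.78). The list passed neither without starch 7 nor without starch 9. The median score per piglet was -0.37 on both diets, and 5 of 11 starch piglets lay above the control median. It passed in 14 alternatives, with means of 0.42 to 0.60 (adjusted p from 0.000219 to 0.0362; adjusted p = 0.915 with an estimated correlation), among them the fits without control 2, 3, 6 or 9 and without starch 1, 2, 3, 5, 6, 8 or 10. T cells and cytotoxic lymphocytes had 22 of 28 members lower (mean -0.07, adjusted p = 0.0532). This list passed in 19 alternatives, with means of -0.25 to -0.07 (adjusted p from 1.36e-05 to 0.0496; adjusted p = 0.915 with an estimated correlation). They included voom (-0.23), surrogate variables (-0.24), the B-cell score as a covariate (-0.20), the fit without control 5, control 8 and starch 3 (-0.25), and those without control 1, 5, 7, 8, 9 or 10 and without starch 3, 4, 9, 10 or 11. Short-chain fatty acid sensing and uptake had 4 of 6 members higher (adjusted p = 0.248), and markers of the vacuolated enterocytes of neonates had 12 of 19 higher (adjusted p = 0.566), among them PIGR, the epithelial carrier of secretory antibody (0.73, 95% interval 0.04 to 1.41). Both passed with the smooth muscle score as a covariate (means 0.33 and 0.26, adjusted p = 0.0484 for each) and the first also without starch 3 (0.10, adjusted p = 0.0429). With an estimated correlation each had an adjusted p = 0.915. In 6 lists the mean log2 fold change and the direction of the camera test differed in sign, and 0 of these passed. They were plasma cells, fatty acid synthesis, ileal bile acid handling, absorptive enterocytes, peptide digestion and glycolysis. In 5 lists the mean and the median of the members differed in sign, namely plasma cells, fatty acid synthesis, ileal bile acid handling, antimicrobial defence and glycolysis.

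The main axis of variation was set by 3 piglets from both diets. Component 1 held 64.0% of the variance of the 500 most variable genes and separated control 5 (score 71.0), control 8 (70.5) and starch 3 (78.6) from the next piglet, starch 4, at 21.3. The absorptive enterocyte list had scores of -2.55, -2.27 and -2.74 in control 5, control 8 and starch 3. FABP6 read 14.9, 40.3 and 0.348 CPM in the same piglets, against a median of 1175 CPM over the 21 piglets. APOA4, an apolipoprotein of chylomicrons, read 16.4, 1.41 and 0.696 CPM (median 519), the microsomal triglyceride transfer gene MTTP 4.88, 3.08 and 0.811 CPM (median 589), and SI 12.8, 22.2 and 16.8 CPM (median 917). The fructose carrier SLC2A5 was not low in them, at 67.7, 36.4 and 73.1 CPM. The list of macrophages, dendritic cells and granulocytes had scores of 1.42, 1.29 and 1.73. At the other end of the component, MMP12, the macrophage elastase, read 206, 399 and 173 CPM (median 2.05), the haemoglobin scavenger receptor CD163 724, 813 and 1027 CPM (median 35.3), CHI3L1 83.3, 119 and 356 CPM (median 2.36) and TGM3 191, 551 and 1034 CPM (median 10.6). Mean scores on component 1 were 0.8 ± 37.9 in control (SD, n = 10) and -0.7 ± 30.2 in starch piglets (SD, n = 11), a difference of -1.47 (two-sided permutation test with 100000 resamples, p = 0.936).

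Component 2, with 7.9% of the variance, had among its strongest genes at one end the interferon-induced OASL, ISG15, IFIT1 and RSAD2, the bile acid genes FABP6, SLC51A and SLC10A2, and MGAM. RBP4, LCN15 and AQP10 stood at the other end. Mean scores were 2.6 ± 9.5 in control and -2.4 ± 13.3 in starch piglets, a difference of -4.95 (permutation test, p = 0.341).

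**Figure D3:**
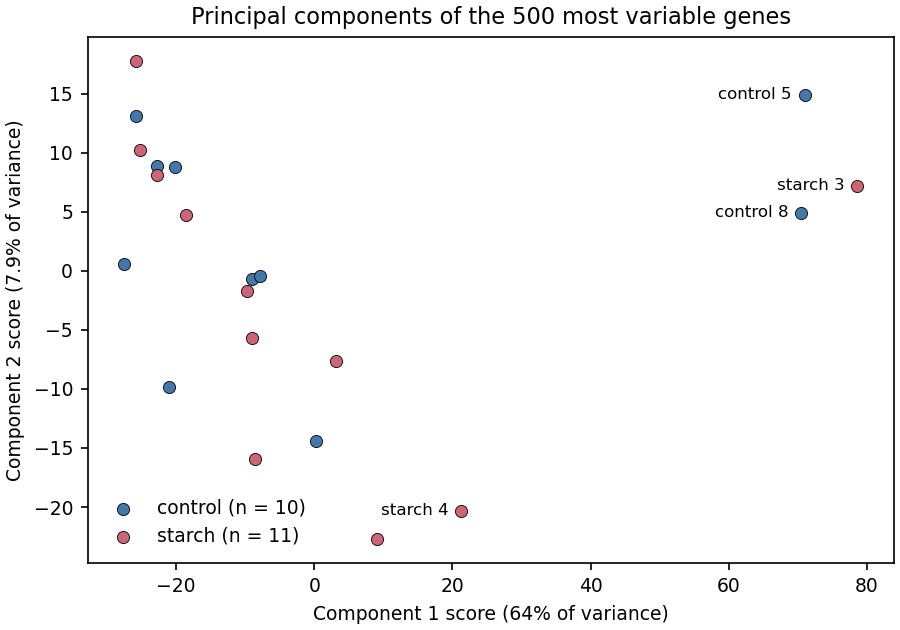
Scores of the 21 piglets on components 1 and 2 of log2 CPM of the 500 most variable genes, coloured by diet. Control 5, control 8 and starch 3 have component 1 scores of 70.5 to 78.6, and the next highest is starch 4 at 21.3.

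**Figure D4:**
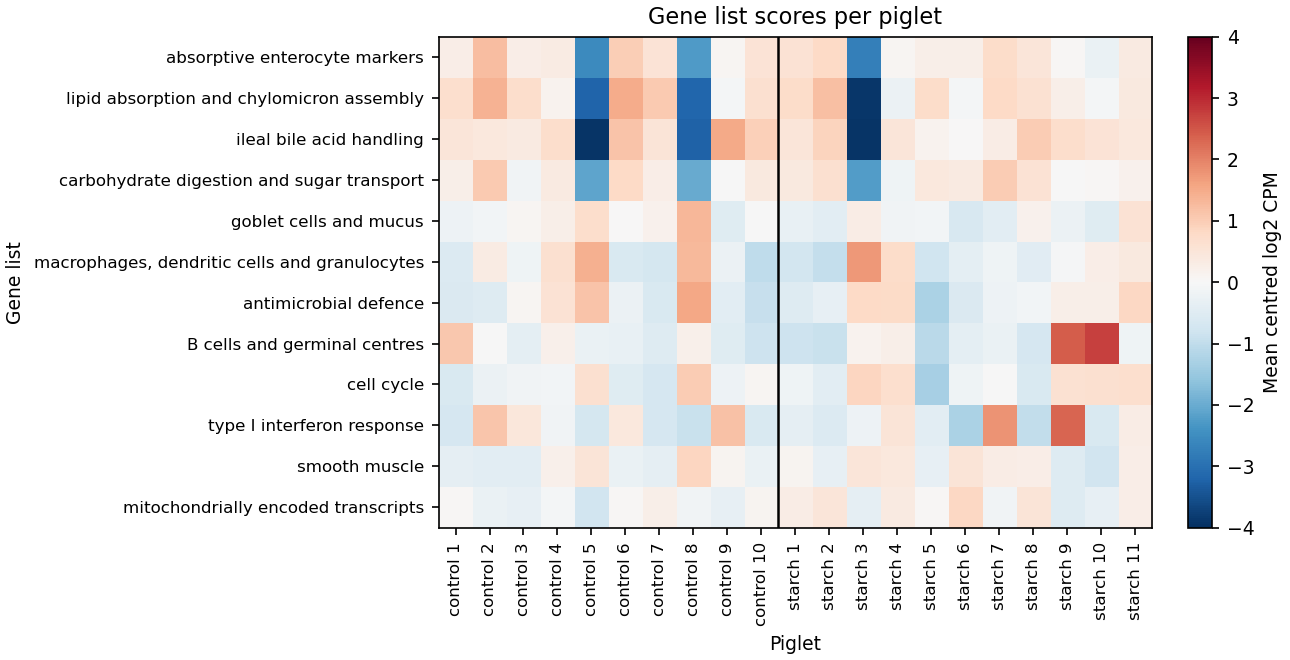
Mean centred log2 CPM of the members of 12 gene lists in each piglet, control on the left and starch on the right of the black line. Absorptive, lipid, bile acid and carbohydrate lists are lowest in control 5, control 8 and starch 3, and the B-cell list is highest in starch 10 (2.74) and starch 9 (2.43).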

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

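The search for extreme piglets used a rule set in advance, and no test in this part was chosen after a result was seen. Within the control group, the gap from the highest or lowest piglet to its neighbour was divided by the whole range and compared with Dixon's critical value for 10 values at the 95% level. The starch group, with 11 piglets, was too large for that rule. Of 75 quantities tested, 4 exceeded the value. Chance gives about 1 in 20, or 4 here, if values are normally distributed. The 29 named genes among them were read as CPM without logs, and most were chosen by their p in these piglets. That rate therefore need not hold for them.

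Control 1 had the highest CPM of AFF2 among controls, 9.42 against 2.65 in the next piglet (gap over range 0.73). It was also highest for FCRL1, a B-cell surface receptor, at 4.64 against 2.63 CPM (0.48). Control 2 was highest for FAF2, at 69.7 against 47.8 CPM (0.6). Control 5 was highest for FERMT1, at 142 against 91.9 CPM (0.47). On component 1, control 5 and control 8 lay close together at 71.0 and 70.5, so neither could exceed the critical value.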

How the results depend on the processing

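The fits without the 3 piglets apart, with a Y-linked covariate, with robust dispersion and without mitochondrial genes, and the comparison of the block with the fit without starch 11, were chosen after the data were seen. The count of changed genes was 0 in 39 of 39 alternatives, with 117 to 686 genes at an unadjusted p of 0.05 and a smallest adjusted p of 0.211 (DESeq2). Of 188 named genes, 149 had the same sign in every alternative, and 0 passed in any. Most of these genes were chosen by their p in the main fit of the same piglets. Agreement in sign was thus largely built in and does not measure reproducibility. The component 1 difference ran from -8.75 to 8.35 (permutation p from 0.35 to 0.989) and that of component 2 from -6.16 to 2.76 (0.261 to 0.895). The list count, 6 in the reported fit, was within 1.5 times of it in 24 of 36 alternatives. It was 10 with voom, 15 with the smooth muscle score as a covariate, 14 without the 3 piglets apart, and 0 with an estimated correlation, with fry, and without the 3 piglets apart with an estimated correlation. Leaving out each piglet in turn gave 4 to 14 lists, with 4 without control 1, 11 without control 2 or control 5, 12 without control 6, 13 without control 8, 14 without starch 3 and 10 without starch 5. The B-cell list mean, 0.90, was -0.138 with surrogate variables and -0.047 with the B cell score as a covariate, which is built from the same genes. The antigen presentation and cell cycle lists were 0.07 and 0.08 with surrogate variables and did not pass (adjusted p = 0.334 and 0.174), and the antigen presentation list did not pass with voom (0.13). For the other alternatives the cause was not tested. With the replicate number as a block there were 0 genes (edgeR, 188 at an unadjusted p of 0.05) and 4 lists, against 0 (203) and 5 for the same piglets without the block; the B-cell list mean was 0.181 with the block (adjusted p = 0.309) and 0.958 without it (adjusted p = 0.000954). The antigen presentation and cell cycle lists passed neither with the block (0.121, adjusted p = 0.39, and 0.126, adjusted p = 0.432) nor without it (0.202, adjusted p = 0.213, and 0.116, adjusted p = 0.309). Same-numbered piglets had residual correlations from -0.34 to 0.48, above 0.1 in 4 of 10 pairs, and 0 of 10 controls lay closest to their own number, so the numbers were not shown to pair piglets. Depth limits mainly genes near the filter, such as TREH.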

Other observations

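The tests in this part were chosen after the results were seen, except that of large intestine markers, whose prediction was written before. The genes and piglets in it were picked after their values were seen.

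Further genes were read in control 5, control 8 and starch 3. REG4, a lectin of secretory cells, read 934, 1944 and 490 CPM, against a median of 72.6 CPM over the 21 piglets, and MUC2 read 779, 1168 and 494 CPM (median 246). DUOX2, an epithelial oxidase, read 112, 68.5 and 18.3 CPM (median 7.17). The anion exchanger SLC26A3 read 1.69, 3.46 and 0.348 CPM (median 121), while the endocrine gene CHGA read 82.6, 176 and 101 CPM (median 155). Of genes of activated myeloid cells, ACOD1 read 32.4, 35.3 and 104 CPM (median 1.395), GPR84 34.5, 88.7 and 558 CPM (median 1.18) and CSF3R 52.9, 94.4 and 155 CPM (median 6.06).

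Interferon-induced genes were high in single piglets of both diets. OASL read 216 CPM in starch 9, 147 in starch 7, 45.2 in control 2 and 33.6 in control 9 (median 2.90), and ISG15 read 323, 194, 85.0 and 111 CPM (median 13.97). The Y-linked KDM5D and EIF1AY were below 1 CPM in 4 of 10 control piglets (2, 5, 7 and 9) and in 4 of 11 starch piglets (2, 8, 9 and 10). B-cell genes were high in starch 9 and starch 10, with POU2AF1 at 77.5 and 106 CPM (median 4.25) and CD79B at 70.1 and 85.0 CPM (median 1.41).

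Among the explanations weighed for the 3 piglets apart on component 1, diet alone is argued against, since 2 of the 3 were on the control diet. A lower share of the whole epithelium is argued against too, since the goblet cell score exceeded the absorptive enterocyte score by 3.26 ± 0.70, 3.61 ± 0.76 and 3.04 ± 0.89 (log2, SE over members) in control 5, control 8 and starch 3. The goblet cell score alone was 0.71 ± 0.34, 1.34 ± 0.34 and 0.30 ± 0.38, so it was not low in them. Members vary together, so this SE is too small, and the piglets were picked on a component on which absorptive genes weigh heavily. Large intestine with its mature absorptive cells is argued against, since SLC26A3 and AQP8, which those cells express strongly, were at most 3.09% of their median over the 21 piglets in each of the 3. Large intestine that had lost those cells stays open. Only 3 of its 11 markers matched a symbol in the files and only 1 passed the filter on low counts, too few for the test. That filter was set on the diet groups, so a marker counted only in these 3 piglets could not have passed it. The prediction as written set no least number of markers, and the least number of 3 used here was added to it. Taken as written, it would have been decided by that 1 marker, whose level is not reported here. A mean of 1 marker is the level of 1 gene, so no conclusion is drawn from it. No explanation beyond these was tested, and the labels give no health record.

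The diet result was set beside 100 splits of the piglets into groups of 10 and 11, the real one included. With a real count of 0 genes (edgeR, 174 at an unadjusted p of 0.05) all 100 had to give as many, so that count tests nothing. The highest other split gave 2312 in the edgeR test. For the real split DESeq2, on 18630 genes without the filter, and voom also called 0, with 293 and 268 at that unadjusted p. For lists, 91 of 100 splits gave 6 or more. The other splits gave 3 to 26 lists with the preset correlation, with a median of 14, so chance cannot be excluded. With an estimated correlation the smallest adjusted p was 0.693, so members that vary together between piglets could account for the list calls. At least 1 gene passed in 4 splits, with 2312, 1384, 159 and 14 genes, and the larger of these counts point to a structure of the samples; 3 of the 4 were among the 27 splits that held control 5, control 8 and starch 3 in one group, and whether that share differs from chance was not tested.

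A differing share of lymphoid tissue was weighed for the cell cycle and antigen presentation lists, which share 0 members with the B-cell list and each had an adjusted p = 0.915 with an estimated correlation. With the B-cell score as a covariate the cell cycle mean went from 0.17 ± 0.16 (SD over members, adjusted p = 0.00929) to 0.05 ± 0.17 (adjusted p = 0.362), which is consistent with that explanation. The antigen presentation mean went from 0.27 ± 0.13 (adjusted p = 0.00694; adjusted p = 0.915 with an estimated correlation) to 0.16 ± 0.16 (adjusted p = 0.14). The antigen presentation call ended as the mean fell, but more than 0.5 of its size was left. For this list lymphoid share, diet and chance cannot be told apart, and an effect of diet on lymphoid tissue itself stays untested. Both calls were also lost when control 7, starch 3, starch 4 or starch 11 alone was left out. Their loss with the B-cell score is therefore not specific to lymphoid share.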
